A study of Homo sapiens with 4 samples.

How the data were processed

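Gene expression was measured on 4 Affymetrix oligonucleotide arrays of human RS4;11 cells, 1 array in each of 4 groups. The groups crossed 2 transductions (control vector, or siRNA number 2 against the long noncoding RNA BALR-2) with 2 treatments (DMSO vehicle, or prednisolone at 250 µg/mL for 12 h). The series design text calls the comparison cells untreated, while the labels name DMSO. The labels were followed, and if no vehicle was given the prednisolone differences also hold any effect of DMSO. Groups were taken from the labels' transduction and treatment entries. The labels name no separate cultures, so p-values measure only the spread between these arrays, which may be technical.

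The deposited values are array intensities on a linear scale, 1 per probe set and array, from 3.31 to 28084. RMA is the method named in the submitters' processing notes, and its version and software are not given in the sources used here. RMA corrects background, equalises the intensity distributions of the arrays and summarises the probes of a probe set, so it removes any overall difference in RNA amount between arrays. Median intensities of the deposited arrays were 63.1 (vector, DMSO), 63.5 (vector, prednisolone), 64.1 (knockdown, DMSO) and 64.4 (knockdown, prednisolone). The number of arrays limits the precision of each value. No column of array values was left out.

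The log2 of each intensity was taken. Of the 54675 probe sets, 41091 had 1 gene in the platform annotation, 1801 had several and 11721 were not listed there and stay unnamed here, and 62 were control probe sets. Symbols of 41037 probe sets were taken through Entrez identifiers from the GRCh38.p14 gene table, whether or not they changed. That table was used for names only. Each of the 19775 genes was represented by its probe set with the highest mean over the 4 arrays, and the 12239 genes with a mean log2 level of at least 6 were tested. More than 1 probe set was listed for 10523 genes. Among the 4702 genes called between transductions, 2385 had several probe sets at or above the level limit, and in 81.8% of these all such probe sets lay in the same direction.

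The effect of prednisolone averaged over both transductions, and of the knockdown averaged over both treatments, were tested with limma 3.58.1 in R 4.3.3, in an additive model of transduction and treatment with 1 residual degree of freedom. Variances were moderated across genes, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The spread in this model is each gene's departure from additivity, so it takes any true interaction as error. Errors are standard errors of that model. The 4 single differences between arrays and the difference of differences (prednisolone difference in knockdown cells minus that in vector cells) have no replicate check and no p-value, and are described by the number of genes at 2-fold or more. Differences between transductions are knockdown minus vector and differences between treatments are prednisolone minus DMSO, on the log2 scale.

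Before the data were examined, 23 gene lists were fixed. For each list the median log2 difference of its measured members is given, with its percentile among 10000 random lists of the same size matched on mean level in 20 bins. A median outside percentiles 2.5 to 97.5 is described as outside the random range. The percentile describes these arrays and is no test between conditions. The genes named were chosen by a rule fixed at the same time. It takes CDK6-AS1, CDK6 and NR3C1, then up to 10 genes with the highest and 10 with the lowest averaged difference among those at 2-fold or more in the same direction in both pairs of arrays. It also takes the 2 highest and 2 lowest members of each list, up to 5 genes at either end of the difference of differences among those at 2-fold or more, and 3 at either end of each single difference. Any other gene is marked as chosen after its values were seen.

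Other settings fixed before the data were examined were no limit on level, a limit of 7, the mean of a gene's probe sets, cyclic loess normalisation, a trended and robust variance, 1.5-fold in place of 2-fold, 2-fold in both pairs in place of the test, list means in place of medians, and leaving out each array. Scaling to the hybridization controls (transcripts added to every sample before hybridization) and leaving out probe sets marked as matching several transcripts were added after seeing the data, as were 3 gene lists used in the closing part. The model was tested on simulated data for the averaged knockdown difference over 12239 genes on 4 arrays. It recovered 100% of 100 genes changed by 1 on the log2 scale and 39% of 100 genes changed by 0.5, with 16 calls among the genes left unchanged and 0 calls for the unchanged treatment. The simulated noise was independent between arrays. It held no error shared by the arrays of one transduction, so the simulation cannot show how many knockdown calls such an error would give.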

Results

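The transcriptome of RS4;11 cells, a human B-lymphoblastic leukaemia line that carries a KMT2A-AFF1 fusion, was measured on 4 arrays. Cells transduced with a control vector and cells transduced with an siRNA against BALR-2 were each given DMSO or prednisolone, a glucocorticoid used against this leukaemia, at 250 µg/mL for 12 h. The design asks which genes differ between cells with this siRNA and vector cells, with and without the drug. No other siRNA was among the arrays, so effects of lower BALR-2 cannot be told apart from other effects of this siRNA. Each group held 1 array. Of 19775 genes, 12239 had a mean log2 level of at least 6 over the 4 arrays and entered the comparisons. Across these genes the arrays of one transduction correlated at r = 0.992 (vector) and 0.994 (knockdown), and the arrays of one treatment at r = 0.974 (DMSO) and 0.971 (prednisolone). Genes are not independent replicates, and these values only describe the arrays.

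BALR-2 is listed as another name of CDK6-AS1, a gene that lies beside CDK6. No probe set carried that name in the annotation used here, so the level of the targeted RNA was not analysed. CDK6, the cyclin-dependent kinase that drives G1 progression, was 1.43-fold lower in knockdown cells (log2 difference -0.52 ± 0.072, limma adjusted p = 0.00585, lower in both pairs of arrays). The 6 CDK6 probe sets above the level limit ranged from -0.78 to 0.00. Of the 5 measured genes in the list of the locus, GATAD1 also fell (-0.27), SAMD9L rose (0.51), and the list median of 0.14 lay inside the random range (percentile 78.2).

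Knockdown cells differed from vector cells in a broad set of genes. HSPA6, an inducible heat shock protein, was 19.8-fold higher (4.31 ± 0.180), the chemokine CXCL8 13.9-fold (3.80 ± 0.105) and the costimulatory ligand TNFSF9 8.02-fold (3.00 ± 0.138). ADM, RGS16, the decoy death receptor TNFRSF10D, the stress-responsive kinase PLK2, the kinase SGK1 and the membrane proteins EMP1 and EMP3 rose by 2.44 to 2.92 on the log2 scale. The lowest gene was SHROOM3, an actin-binding protein, at 8.64-fold lower (-3.11 ± 0.123), followed by NRXN3 (-2.44 ± 0.297), the transcription factor ERG (-2.05 ± 0.112), CACNA2D1 (-2.04), LGR5 (-2.02) and the survival gene BCL2 (-1.96 ± 0.078). SORBS2, VASH2, VAV3 and MBNL3 fell by 1.78 to 1.89 on the log2 scale. For BCL2 the probe sets disagreed, from -1.96 to 0.06. A second probe set gave a smaller difference for HSPA6 (2.49), CXCL8 (1.98), RGS16 (1.45) and SHROOM3 (-2.24). With limma, 4702 of 12239 genes changed (2378 higher and 2324 lower, adjusted over all genes tested), of which 223 higher and 181 lower were at 2-fold or more on average. The count was 2332 without a limit on level, and 291 genes reached 2-fold in the same direction in both pairs. The 18 probe sets of the hybridization controls, which do not come from the cells, were also higher by 0.37 on average in the knockdown arrays (0.44 under DMSO, 0.29 under prednisolone). Scaled to them, 7.36% of 8258 called genes were higher, against 50.6% of the 4702. Because the controls differed unequally in the pairs of arrays, this scaling shifts every gene's departure from additivity, the spread of the model, by the same amount. Its calls are therefore not comparable with the 4702, and no fall of most genes is concluded from them.

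Genes of DNA replication fell almost as a block. Of 29 measured genes of the G1/S list, 28 fell and 1 rose, and the median was -0.85 (1.80-fold lower, percentile 0). CCNE2, the cyclin of the G1/S transition, was 3.33-fold lower (-1.73 ± 0.083) and the uracil-DNA glycosylase UNG 2.93-fold lower (-1.55 ± 0.116), while the sliding clamp PCNA fell by 0.46. The member that rose was CCND2, a D-type cyclin (1.80 ± 0.089). Its mean log2 level was 6.65, near the limit of 6, and its other probe sets, under the limit, were at 0.02 to 0.12. Of 30 mitotic genes, 24 fell and 6 did not pass the test, with a median of -0.61 (percentile 0). That median was -0.37 under DMSO, with no member 2-fold lower, and -0.83 under prednisolone, with 8 members 2-fold lower. AURKB (-1.07 ± 0.112) and HMMR (-0.94 ± 0.145) fell, and TTK (-0.23, adjusted p = 0.241) and AURKA (-0.28, adjusted p = 0.161) did not pass. In the list of MYC and ribosome biogenesis 13 of 25 genes fell and none rose (median -0.27, percentile 0), among them MYC itself (1.97-fold lower, -0.98 ± 0.074) and NME1 (-0.87). FBL and PES1 were at 0.18 and 0.04 and did not pass. The counts were the same when adjusted over the list alone.

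Targets of p53 and inhibitors of cyclin-dependent kinases rose together. Of 22 measured members 17 rose, none fell and 5 did not pass, with a median of 0.96 (1.94-fold higher, percentile 100). Both death receptors of the list were among the highest, FAS at 3.69-fold (1.88 ± 0.075) and TNFRSF10B at 3.15-fold (1.66 ± 0.073), although the TNFRSF10B probe sets ranged from -0.01 to 1.81. The inhibitors CDKN1B (-0.00) and CDKN2A (-0.19, adjusted p = 0.32) did not pass. In the BCL2 family 5 of 13 genes rose and 2 fell (6 and 2 when adjusted over the list alone). The pro-apoptotic genes BAX (1.05 ± 0.098) and PMAIP1 (0.65 ± 0.085) rose, whereas BCL2 and the pro-apoptotic BID (-0.27 ± 0.074) fell. Its median of 0.21 lay inside the random range (percentile 96.4), with 0.26 above the range under prednisolone (percentile 98.95).

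Immediate-early genes had a list median of 1.06 in the averaged difference (2.09-fold higher, percentile 100), from 0.79 under DMSO and 0.93 under prednisolone. Of 23 members 15 rose and 3 fell (17 and 3 when adjusted over the list alone). FOS, a subunit of AP-1, was 5.38-fold higher (2.43 ± 0.092) and the stress factor ATF3 3.91-fold higher (1.97 ± 0.124, with a second probe set at 1.05), while the phosphatase DUSP1 (-0.67 ± 0.081) and MYC fell. Of 26 genes of the amino acid and unfolded protein responses, 17 rose and 1 fell (median 0.57, percentile 100, and the same counts when adjusted over the list alone). TRIB3, a pseudokinase induced by ATF4, rose 3.15-fold (1.66 ± 0.087), and XBP1, a factor of the unfolded protein response and of plasma cell differentiation, fell (-0.49 ± 0.083). In the list of NF-kB targets 9 of 16 genes rose and 3 fell (10 and 3 when adjusted over the list alone), with a median of 0.39 (percentile 100). CXCL8 and RELB (0.85 ± 0.180) rose, and the feedback inhibitor TNFAIP3 (-0.93 ± 0.083) and the cytokine LTB (-0.81 ± 0.164) fell. LTB was at 0.08 when probe sets matching several transcripts were left out.

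Genes of B-precursor identity were mostly lower, with 19 of 32 down, 3 up and 10 not passing, and a median of -0.46 (percentile 0). Adjusted over the list alone, 22 fell and 4 rose. ERG and the B cell adaptor BLNK (-1.58 ± 0.119, 2.99-fold lower) fell most, whereas the cytokine receptor CRLF2 (0.62 ± 0.086) and the B cell receptor subunit CD79A (0.53 ± 0.087) rose. Of 22 genes associated with KMT2A fusions 13 fell and 4 rose, with the same counts when adjusted over the list alone and a median of -0.35 (percentile 0). The receptor kinase FLT3 was 1.95-fold lower (-0.96 ± 0.072) and BCL2 fell, while RUNX2 (1.45 ± 0.074) and CPEB2 (0.75 ± 0.085) rose. RUNX2 had a mean log2 level of 6.46, near the limit of 6. Its other probe sets, under the limit, ranged from -0.17 to 0.23. Of 35 genes known to be induced by glucocorticoids, 16 rose and 4 fell, with the same counts when adjusted over the list alone and a median of 0.25 (percentile 100). SGK1 and ANXA1, an anti-inflammatory annexin (2.16 ± 0.086), rose, and the cyclin CCND3 (-1.18 ± 0.117) and SNTB2 (-0.78 ± 0.077) fell. CCND3 had a second probe set at -0.29. The list median was 0.15 under DMSO and 0.27 under prednisolone. Averaged, it was -0.02 when probe sets matching several transcripts were left out, and -0.12 when arrays were scaled to the hybridization controls, which moved the median of all genes to -0.36. The glucocorticoid receptor gene NR3C1 did not pass (-0.01 ± 0.094, adjusted p = 0.936). Of 17 genes of the receptor and its co-factors 1 rose and 4 fell, FKBP5 being the lowest (-0.78 ± 0.096), with a median of -0.11 (percentile 12.1).

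Markers of other cell types stayed inside the random range as lists. The median was 0.05 for 8 T and NK cell markers (percentile 71.7), 0.16 for 4 monocyte and granulocyte markers (percentile 87.5), -0.03 for 6 erythroid and platelet markers (percentile 31.6) and 0.15 for 6 fibroblast and epithelial markers (percentile 88.0). Single members did change, such as MPO, the granule peroxidase, at 3.20-fold lower (-1.68 ± 0.072), ITGAM (0.76), ITGA2B (0.63), NKG7 (0.67), LCK (0.48), ACTA2 (0.89) and TAGLN (0.58, probe sets from 0.03 to 1.16). Medians also lay inside the range for interferon response genes (0.14, percentile 95.7, with IRF7 at 0.97 and CMPK2 at -1.22), cholesterol synthesis (0.16, percentile 96.0), glycolysis (0.05, percentile 73.1), lymphoid signalling and migration (0.05, percentile 71.7), the small RNA pathway (0.07, percentile 73.9) and housekeeping genes (-0.03, percentile 35.2). Within glycolysis the transporter SLC2A3 (1.60 ± 0.094) and ENO2 (1.39 ± 0.072) rose.

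The knockdown difference was measured separately under each treatment, without a test. Under DMSO 208 genes were at least 2-fold higher and 193 at least 2-fold lower, and under prednisolone 259 and 210. HSPA6, CXCL8 and SHROOM3 were among the 3 most extreme genes at their end in both treatments. HSPA6 was at 3.93 under DMSO and 4.69 under prednisolone, CXCL8 at 3.97 and 3.62, and SHROOM3 at -2.88 and -3.34. The 2 single differences, which share no array, correlated at r = 0.88 across genes. Both compare the same 2 transductions, each possibly 1 culture, so an error common to a transduction would also raise this value.

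**Figure D1:**
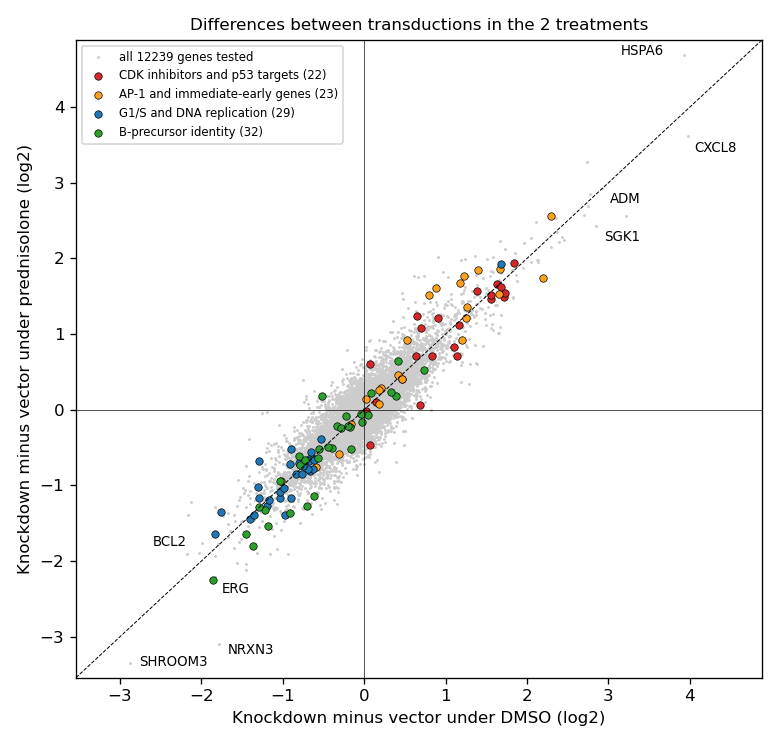
Each point is 1 of 12239 genes, placed by its log2 difference between knockdown and vector cells under DMSO (horizontal) and under prednisolone (vertical), with 1 array per group and 4 gene lists coloured. The dashed line marks equal differences, and 28 of 29 genes of the G1/S list lie below 0 on average while 20 of 22 p53 targets and kinase inhibitors lie above it.

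Prednisolone was compared with DMSO to ask what the drug did in these cells. Averaged over both transductions, 7 genes differed by 2-fold or more, and 3 did so in the same direction in both pairs of arrays. These were the phospholipase PLD1 (1.41 in vector and 1.02 in knockdown cells), SEPTIN7P14 (1.03 and 1.01), and the potassium channel subunit KCNMB1 (-1.09 and -1.20). The SEPTIN7P14 probe sets disagreed, from -0.03 to 1.02 on average, and those of PLD1 ranged from 0.57 to 1.22. With limma no gene passed (0 of 12239, lowest adjusted p = 0.0713), while 2800 genes had an unadjusted p under 0.05 against 612 under chance. The count stayed at 0 without a limit on level. It was 454 with a trended and robust variance, 692 with a level limit of 7, 123 after cyclic loess and 94 with the mean of a gene's probe sets.

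Among genes known to be induced by glucocorticoids, the response was small and went both ways. The median of the 35 members was 0.09 (1.06-fold, percentile 99.9), from 0.07 in vector cells (percentile 96.8) and 0.09 in knockdown cells (percentile 100). Adjusted over the list alone, 4 members were higher and 4 lower, against none over all genes. TBL1X (0.50 ± 0.096) and IRS2 (0.49 ± 0.072) were highest, whereas TXNIP, an inhibitor of thioredoxin (-0.67 ± 0.072), and FKBP5, a receptor co-chaperone (-0.52 ± 0.096), were lowest. TSC22D3, a leucine zipper protein named after its value was seen because it is a widely used marker of glucocorticoid exposure, was at -0.03 in vector and 0.01 in knockdown cells. NR3C1 was higher by 0.31 ± 0.094 (adjusted p = 0.156) and BCL2L11, a pro-apoptotic gene of the glucocorticoid response in lymphoid cells, was at -0.28 in vector and 0.01 in knockdown cells (adjusted p = 0.451). The 6 BCL2L11 probe sets above the level limit disagreed, from -0.14 to 0.40 averaged over both transductions, and one of them was at 0.02 in vector and 0.78 in knockdown cells.

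Other gene groups were further from 0 under prednisolone, again with no member passing over all genes. The 3'/5' log2 ratio of ACTB, a sign of RNA quality, was also higher under prednisolone, by 0.25 in vector and 0.13 in knockdown cells, and that of GAPDH by 0.04 and 0.02. DNA replication genes were lower, with a median of -0.24 (percentile 0) and 26 of 29 members below 0 in knockdown cells and 25 in vector cells. Adjusted over the list alone, 14 passed, all lower, with CLSPN (-0.71 ± 0.097) and CCNE2 (-0.59 ± 0.083) at the bottom. All 25 genes of MYC and ribosome biogenesis were below 0 in vector cells and 23 in knockdown cells (median -0.20, percentile 0, 8 lower when adjusted over the list alone). TFRC, the transferrin receptor (-0.50 ± 0.078), and SRM, spermidine synthase (-0.47 ± 0.072), were lowest. Genes of the amino acid and unfolded protein responses were higher, at a median of 0.32 in vector and 0.10 in knockdown cells (both percentile 100, 4 higher when adjusted over the list alone). The cystine transporter SLC7A11 (0.85 ± 0.117) and the glutathione-degrading CHAC1 (0.85 ± 0.194) led this list. Of the remaining lists, 2 had a median below the random range, p53 targets and kinase inhibitors at -0.10 (percentile 0.7, TIGAR at -0.60) and the 4 monocyte and granulocyte markers at -0.21 (MPO at -0.78, adjusted p = 0.0713). Mitotic genes, at 0.12 (percentile 100), are described with the difference of differences. The other 16 lists lay inside the range on average, with percentiles from 3.58 to 96.5. In single pairs of arrays 2 of them lay outside it, immediate-early genes in vector cells (-0.17, percentile 0.04) and cholesterol synthesis in knockdown cells (0.11, percentile 97.8). Among their members, RUNX2 (0.75 ± 0.074), FLT3 (0.42 ± 0.072) and EGR1 (0.48 ± 0.072) were higher, and KLF10 (-0.83 ± 0.174), BID (-0.62 ± 0.074), IL1B (-0.59 ± 0.075), TNF (-0.58 ± 0.081) and LCK (-0.56 ± 0.072) were lower.

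**Figure D2:**
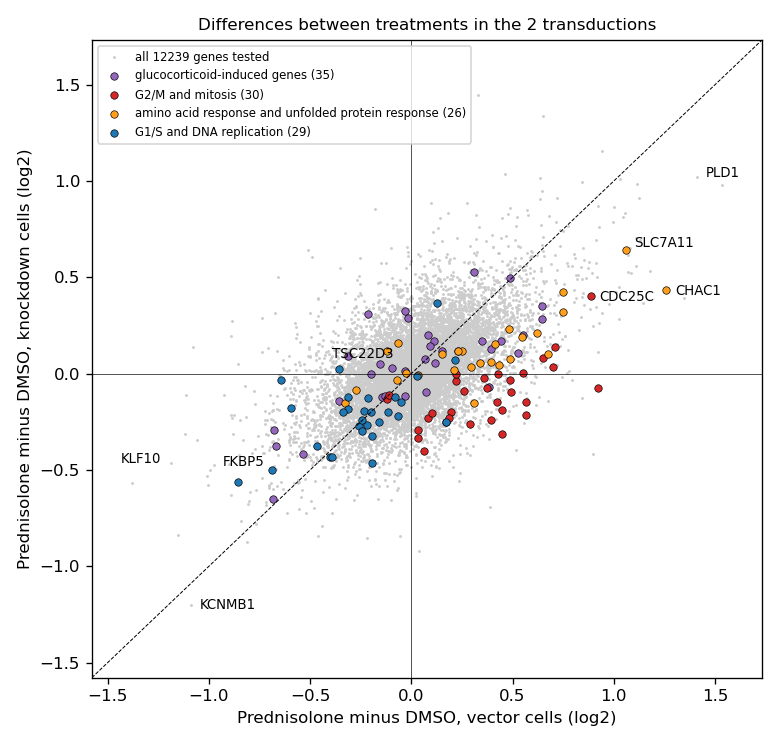
Each point is 1 of 12239 genes, placed by its log2 difference between prednisolone and DMSO in vector cells (horizontal) and knockdown cells (vertical), with 1 array per group and 4 gene lists coloured. The 30 mitotic genes all lie below the dashed line of equal differences, and the 35 glucocorticoid-induced genes spread around 0 in both transductions.

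In single pairs of arrays prednisolone was followed by 22 genes at least 2-fold higher and 10 at least 2-fold lower in vector cells, and by 7 and 1 in knockdown cells. In vector cells VWA8 (1.53), PLD1 and the stress regulator CREBRF (1.35) were highest, and the growth factor BMP2 (-1.38), KLF10 (-1.19) and the scavenger receptor SCARF1 (-1.15) were lowest. The SCARF1 value comes from a probe set marked as matching several transcripts, and its other probe set was at -0.34. In knockdown cells the intestinal enzyme gene MGAM (1.45) and the noncoding OSER1-DT (1.34, with a second probe set at -0.02) and GALNT7-DT (1.16) were highest, and KCNMB1, KIF7 (-0.92) and PPARGC1B (-0.87) were lowest. These counts were not compared by a test. Across genes the 2 single differences correlated at r = 0.55.

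Whether the drug acted differently in knockdown cells can only be described, since the design leaves no array to estimate an error. Mitotic genes stood apart. Under prednisolone their median was 0.38 in vector cells (28 of 30 above 0, percentile 100) and -0.12 in knockdown cells (25 of 30 below 0, percentile 0.2), and all 30 had a negative difference of differences (median -0.47, percentile 0). The phosphatase CDC25C was at 0.89 in vector and 0.40 in knockdown cells, HMMR at 0.71 and 0.14, and the proliferation marker MKI67 at 0.06 and -0.40. Another MKI67 probe set was at -0.02 and -0.12. Genes of the amino acid and unfolded protein responses were also lower in this comparison (median -0.26, percentile 0, 20 of 26 negative), with CHAC1 at 1.26 in vector and 0.44 in knockdown cells. The lists of glycolysis (0.09, percentile 100), the BCL2 family (0.14, percentile 98.9) and immediate-early genes (0.08, percentile 97.7) lay above the random range, the last of these from -0.17 in vector cells (percentile 0.04, below the random range) and -0.04 in knockdown cells (percentile 15.3), and at -0.03 in the difference of differences when probe sets matching several transcripts were left out. The other 18 lists lay inside it. Of 12 genes whose difference of differences reached 2-fold, 10 were positive and 2 negative. NRTN (1.21), ARSB (1.16), the death receptor TNFRSF10A (1.16), AGBL3 (1.15) and MGAM (1.12) were highest, and NRXN3 (-1.31) and ZNF800 (-1.08) were lowest. A second probe set gave 0.18 for TNFRSF10A and -0.21 for ZNF800, and those of ARSB and AGBL3 are marked as matching several transcripts. With a level limit of 7 the count was 3, and without a limit 41.

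**Figure D3:**
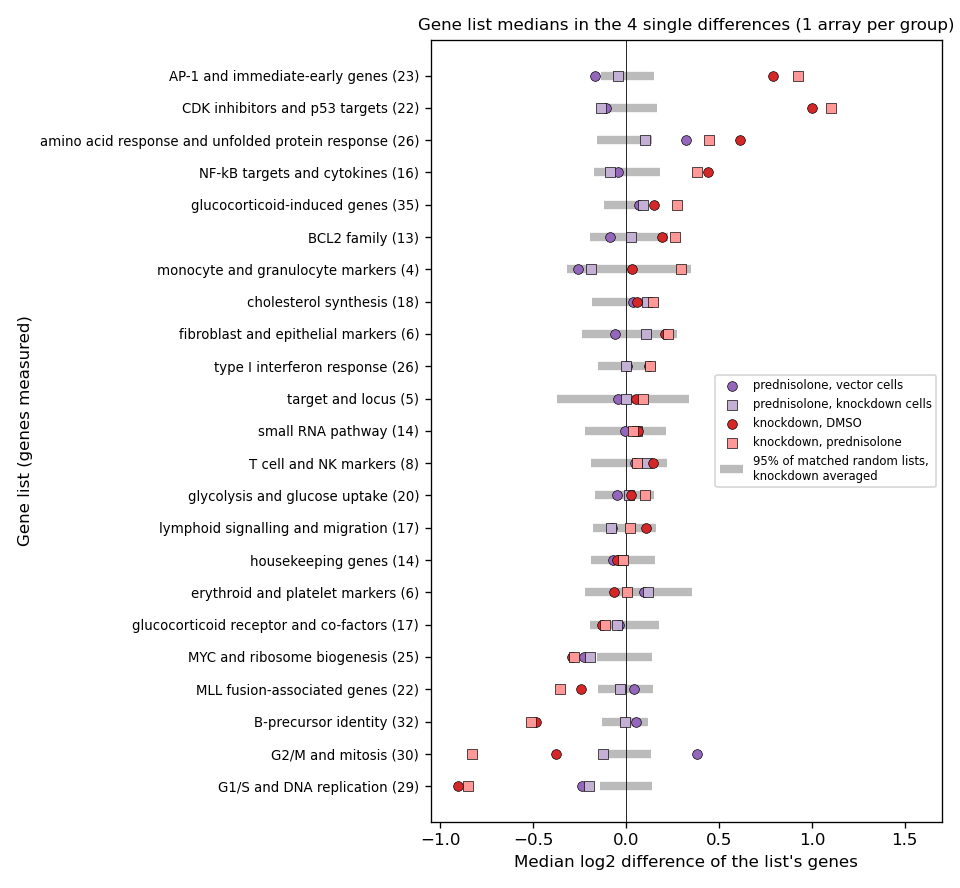
Median log2 difference of each of 23 gene lists (rows, with the number of genes measured) in the 4 single differences, with grey bars for the central 95% of matched random lists in the averaged knockdown difference. Replication genes lie at -0.90 and -0.85 between transductions and at -0.23 and -0.20 between treatments, while mitotic genes lie at 0.38 under prednisolone in vector cells and at -0.12 in knockdown cells.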

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

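The tests of NR3C1's level and of the measuring range over the whole list were planned before their values were seen. The other tests in this part were chosen after the results were seen, among them that of the range for members higher in knockdown cells.

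Knockdown cells differed from vector cells in 4702 genes, and the 18 hybridization controls, a measure outside the cells, also differed by 0.37 between transductions against at most 0.097 between treatments. A single scale difference between arrays is argued against, since it would move all genes alike and so cannot alone give both higher and lower genes. The p53 and DNA replication lists lay 1.80 apart on the log2 scale. They were picked with their values known, so this restates the pattern and is no separate support. RNA degradation is argued against for the 2 transcripts checked, since the 3'/5' ratios of ACTB and GAPDH differed by at most 0.0878 (log2) between transductions. Control probe sets of ribosomal RNA did differ between transductions, by 0.82 for the 5' part of 28S and -0.32 for 18S. Whether this reflects RNA quality was not tested. A separate culture or hybridization of each transduction cannot be told apart from the knockdown, because each transduction may be 1 culture and the hybridization controls split the same way by 0.37. Lower BALR-2 itself stays open, with 0 probe sets named for it in the annotation used here.

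Genes known to be induced by glucocorticoids lay near 0 under prednisolone, with a median of 0.09. Target genes already at the top of the measuring range are argued against in vector cells for 16 of the 35 members. These were picked because they read above their vector DMSO level in the knockdown arrays (median 0.72 higher under DMSO, limma over both treatments). Under prednisolone they had a median of 0.16 on average, 0.19 in vector and 0.12 in knockdown cells. For knockdown cells, where they were already raised, this says nothing on the range. For the other 19 members the planned test decides nothing. The share of the list above the 95th percentile of level (11.4%) sets different probe sets against each other. Absence of the receptor transcript is argued against, since 5 NR3C1 probe sets lay above the level limit. Their mean log2 levels ran from 7.46 to 9.92. The rank of NR3C1 by level (percentile 69.7) compares different probe sets and adds little. These levels say nothing on the receptor protein. An exchange of the prednisolone and DMSO arrays in both transductions is argued against as the reason for a list median near 0. It would only reverse the sign of each difference, so it cannot bring a responding list near 0. The list's percentiles were 96.8 in vector cells, inside the random range, and 99.95 in knockdown cells. With the vector value inside the range, they do not decide whether the arrays were exchanged. Members went both ways, with 4 higher and 4 lower when adjusted over the list alone, so nothing is concluded for single members. A weak response of the line at this time stays open as an untested biological explanation.

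By median, mitotic genes were higher under prednisolone in the vector arrays and lower in the knockdown arrays, a difference of -0.47 that was not tested. A change in the share of dividing cells that moves replication and mitotic genes together is argued against, since DNA replication genes had a difference of differences of -0.0166. A shift of cells between phases of the cycle was not tested. In vector cells under prednisolone the median was -0.23 for replication genes and 0.38 for mitotic genes. A single deviating array cannot be told apart from an effect of the knockdown on the response, because with 1 array per group both give the same value of -0.47.

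The other prednisolone differences that stood out had opposite signs in vector and knockdown cells, and none was tested. NRTN (1.21), TNFRSF10A (1.16), ARSB (1.16) and AGBL3 (1.15) had positive differences of differences, and NRXN3 (-1.31) and ZNF800 (-1.08) negative ones. A second probe set gave 0.18 for TNFRSF10A and -0.21 for ZNF800. NRTN was at -1.08 in vector and only 0.14 in knockdown cells. Signs were also opposite for the list medians of the BCL2 family (0.14) and of glycolysis (0.087). Within each transduction these medians lay near 0 and inside the random range. They were -0.08 in vector and 0.03 in knockdown cells for the BCL2 family, and -0.05 and 0.02 for glycolysis. Outside the gene comparisons, a control probe set for the 5' part of 28S ribosomal RNA was higher by 0.82 in knockdown arrays (0.78 under DMSO, 0.86 under prednisolone), while those for 18S ribosomal RNA were at -0.32.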

How the results depend on the processing

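The alternatives that scale to the hybridization controls or leave out probe sets matching several transcripts were chosen after seeing the data. The count of 10 lists outside the random range for the knockdown was 14 without a level limit, 13 with the mean of a gene's probe sets, and 10 with a level limit of 7, after cyclic loess, with list means and without probe sets matching several transcripts, and these counts do not say which lists. Hybridization control scaling moves all averaged knockdown differences alike, so it cannot change a list's percentile and says nothing about that count, although 47 list medians moved and 1 reversed under it. It also shifts every gene's departure from additivity by the same amount. The errors of the model come from that departure, so the numbers of genes called under this scaling are not comparable with the others. The cause was not tested for any change below, except where fewer genes, fewer arrays or a lower limit are part of the setting. Genes called for prednisolone (0) stayed at 0 without a level limit. They numbered 692 with a level limit of 7, 94 with the mean of a gene's probe sets, 123 after cyclic loess, 638 with hybridization control scaling, 27 without probe sets matching several transcripts and 454 with a trended and robust variance. Genes called for the knockdown (4702) numbered 2332 without a level limit and 8258 with hybridization control scaling (608 higher and 7650 lower, median of all genes -0.36), and 3643 to 5193 in the other settings that kept the test. Counting genes at 2-fold in both pairs in place of the test gave 3 for prednisolone and 291 for the knockdown. Leaving out 1 array leaves no residual degrees of freedom, so the single difference that remains is counted at 2-fold, which gave 8 to 32 genes for prednisolone and 401 to 469 for the knockdown. With the mean of a gene's probe sets the counts at 2-fold were 16 (prednisolone in vector cells, 32 as reported), 3 (in knockdown cells, 8 as reported), 261 (knockdown under DMSO, 401 as reported) and 5 (difference of differences, 12 as reported). In knockdown cells prednisolone gave 27 genes without a level limit and 5 with a limit of 7, and the difference of differences 41 and 3. Hybridization control scaling gave 15 (prednisolone in knockdown cells), 1026 and 706 (knockdown under DMSO and prednisolone) and 19 (difference of differences). At 1.5-fold the counts were 315 and 149 for prednisolone in vector and knockdown cells, 1574 and 1674 for the knockdown under DMSO and prednisolone, and 185 for the difference of differences. The glucocorticoid-induced list reversed for the knockdown to -0.12 with hybridization control scaling and to -0.0172 without probe sets matching several transcripts. The immediate-early list reversed in the difference of differences to -0.0328 and LTB to 0.0819 in that last setting. With hybridization control scaling, which lowers all averaged knockdown differences alike by 0.37, MSMO1 (-0.0113), NCOA1 (-0.0648), DOT1L (-0.0647) and IL1B (-0.0028) reversed for the knockdown. Genes with a mean log2 level under 6, 7536 of 19775, were left out of the main results, and no statement is made on them.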

Other observations

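The 3 lists of this part, and all tests in it, were chosen after the results were seen. The genes that prompted each list (ADM and P4HA2, HSPA6, H2AC6) were left out of it after it had first been run with them. Put back, they left the hypoxia list at 0.94 (percentile 100) and the heat shock list at 0.04 (percentile 65.4) for the knockdown.

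Genes of the hypoxia response were higher in knockdown cells, a group outside the 23 fixed lists. Of 18 measured members, 3 of which also stand in a fixed list, 14 rose and 1 fell. The median was 0.86 (0.85 under DMSO and 0.90 under prednisolone), at percentile 100 of matched random lists. ADM, a vasodilator peptide gene, and the collagen hydroxylase subunit P4HA2 (2.12 ± 0.072) had prompted the list. Under prednisolone its median was 0.17, with 14 of 18 members above 0 in either transduction. A candidate explanation for ADM and P4HA2 is a response of the listed genes as a group, which the percentile of 100 goes with. It speaks only for the members of this list. The fixed list of glycolysis and glucose uptake lay inside the random range for the knockdown (0.05, percentile 73.1). Of its 20 measured genes 5 rose and 4 fell. The comparison of transductions is open to the same confounding by culture or hybridization as the other knockdown differences.

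HSPA6 was the highest gene of the knockdown. The 15 other measured heat shock genes, 4 of which also stand in a fixed list, had a median of -0.02 at percentile 41.7, with 3 members higher and 1 lower. Under DMSO the median was -0.07 (percentile 21.3) and under prednisolone 0.18 (percentile 98.1, 10 of 15 members above 0), so whether heat shock genes were higher as a group stays open. Between treatments the heat shock list lay at -0.27 in vector cells, below the random range (percentile 0), at -0.06 in knockdown cells, inside it (percentile 20.2), and at -0.17 on average (percentile 0.04).

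H2AC6, a histone gene, was higher under prednisolone in both transductions (0.92 and 0.87). Of 9 other measured histone genes 8 were above 0 in vector cells and 7 in knockdown cells, and the averaged median of 0.13 lay inside the random range at percentile 94.98. The median was 0.21 in vector cells, above the random range at percentile 99.4, and 0.12 in knockdown cells, inside it at percentile 88.2. Whether histone genes were higher as a group stays open, since the pairs of arrays fall on either side of the limit. With H2AC6 put back the averaged median of the 10 genes was 0.21 at percentile 99.8. With H2AC6 left out, 3 of the 9 were higher when adjusted over the list alone, and over all genes none passed. RNA45SN5, the ribosomal RNA precursor, chosen after its values were seen, was higher by 2.35 ± 0.085 in knockdown cells and by 1.12 and 0.91 under prednisolone in vector and knockdown cells, from a probe set marked as matching several transcripts. A second probe set without that mark was higher by 2.04 in knockdown cells and by 0.55 and 0.84 under prednisolone.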
